A study of Homo sapiens with 3 samples.

How the data were processed

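Small RNA libraries were made from total RNA of CAL-27 clones with a ligation-based small RNA kit from New England Biolabs, size-selected after PCR and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Bowtie and the GRCh38 build are named in the submitters' processing notes with no role or version. Adapter trimming, the miRNA reference, the mismatches allowed, the treatment of reads that match several miRNAs and the reads counted in the per-million total are not given in the sources used here. No molecular identifiers are mentioned in the labels, so PCR copies are counted as reads.

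The deposited table gives 1149 mature human miRNAs in 3 columns, which the authors call TPM. The deposited values behave as RPM, the number of reads per 1000000 reads of a library total: each of the 1149 values of a library was a whole multiple, within 0.01 of a read, of a step shared by all miRNAs whatever their length. That step was 0.0929 rpm in CC, 0.0940 in Mock and 0.0955 in RR, so whole reads were recovered for 100% of values and the total behind the scale follows from the step. The columns sum to less than the scale they are on, which means that the total holds reads outside the listed miRNAs. Reads of the listed miRNAs came to 1750776 in CC, 2462835 in Mock and 2147869 in RR.

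Columns were assigned to libraries through the treatment tag of the labels, and groups follow the titles (CC, Mock, RR). The treatment tags of Mock and RR leave their assignment in doubt, as described with the results, and the deposited labels were kept. With 1 library per group no test across replicates exists, and no count model was fitted. Values are therefore given as rpm with exact 95% Poisson intervals from the recovered reads, and ratios with exact intervals from the Clopper-Pearson limits of the share of reads. An interval of a ratio compares 2 libraries, not the conditions. Log2 ratios were taken after adding 1 rpm, which understates changes of miRNAs with few reads; folds printed with an interval use the values as deposited. Counts cover miRNAs with a mean of 10 rpm or more over the 3 libraries (208 miRNAs) and a log2 ratio of 1 or more in size, which is 2-fold. All miRNAs so counted also had a counting interval that excluded 1.

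These choices, 21 miRNA lists, 6 lists of cell type markers, the rule for named miRNAs and a first set of alternatives were made before the data were examined. The rule names both arms of miR-21, the 10 miRNAs with the highest mean, for RR over CC the 10 largest ratios each way and for the other comparisons the 6 largest each way, all with a mean of 100 rpm or more and 2-fold or more, of the miRNAs with RR apart from both others the 6 largest each way, again with a mean of 100 rpm or more, and up to 4 measured members per list by their RR over CC ratio. miRNAs outside it that the text names were chosen after their values were seen: miR-550a-5p, miR-3182, miR-103b, miR-193b-3p, miR-320c, miR-296-5p, miR-139-5p, miR-34a-5p, miR-143-3p, miR-122-5p, miR-451a, miR-144-3p, miR-133a-3p, miR-142-3p, miR-142-5p, miR-150-5p, miR-199a-5p and both arms of miR-185, and hairpins or family members given for comparison. The median log2 ratio of each list with 3 or more measured members was set against 10000 random lists of equal size, matched on mean expression by deciles, as a description of these libraries.

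Alternatives were a pseudocount of 0.1 or 10, a mean of 1 or more, no filter or a mean of 100 or more, thresholds of 1.5-fold and 4-fold, division by the median ratio to the geometric mean, and scaling to a common total without the 10 most abundant miRNAs. A linear GC trend removed from each library, values as a share of the miRNA reads, and a filter on CC and RR alone were added after the data were seen. GC content was taken from the sequences in the table. Mature sequences of the leading miRNAs were searched in the hairpin transcripts of GENCODE release 29 (GRCh38) for coordinates, and all 25 searched were found, 6 of them in several hairpins. Near-identical miRNAs were those with at most 2 mismatches over 18 or more bases.

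The counting rules were tried on simulated reads drawn, with counting error alone, from the mean levels of the 3 libraries. Beyond the planted changes no difference between cultures, in GC bias or in composition was simulated. The outcome was thus close to fixed in advance and checks the computation only. For RR over CC, with 1149 miRNAs run, 19 of 19 miRNAs changed 3-fold and 24 of 24 changed 6-fold that passed the filter were recovered, and 0 of 172 unchanged ones were counted. For Mock over CC the counting interval covered 1 in 205 of 215 unchanged miRNAs. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Isomirs, other small RNAs and mRNA targets were not analysed here.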

Results

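Mature microRNAs were measured by small RNA sequencing in clones of CAL-27, an established human line from a squamous cell carcinoma of the tongue. There were 3 libraries, with 1 library in each of 3 groups, so no difference has a replicate check and no p-value is given. CC was an untreated control. The library labelled Mock came, by the series' design text, from cells given a single X-ray dose of 2 Gy. RR was the radioresistant group, which received 2 Gy a day over 2 cycles of 5 days, with a recovery of 2 weeks after each cycle. The labels do not say whether a library held a single clone or several. The treatment tags of the Mock and RR libraries do not settle which is which: the tag naming a 2 Gy dose stands on RR, which received that dose daily, and the tag naming irradiation without a dose stands on Mock. Every direction given for Mock or RR therefore refers to the library labelled so.

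The libraries held 10769990 reads for CC, 10632785 for Mock and 10473400 for RR, by the total behind the per-million scale. Reads of the 1149 listed miRNAs made up 16.3% of that total in CC (Wilson 95% interval 16.2% to 16.3%), 23.2% in Mock and 20.5% in RR. At least 1 read was found for 867 miRNAs in CC, 895 in Mock and 886 in RR. Intervals, here and elsewhere, cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. A count of 3 reads, taken as the floor, corresponded to 0.279 rpm (reads per 1000000 reads of the total) in CC, 0.282 in Mock and 0.286 in RR.

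The miRNA pool was that of a squamous epithelial line in all 3 libraries, with miR-205-5p, a miRNA of stratified epithelia, and miR-200c-3p, which holds back the mesenchymal factors ZEB1 and ZEB2, among the most abundant. miR-205-5p stood at 25945 rpm in CC, 14174 in Mock and 29651 in RR, and miR-200c-3p at 11739, 13918 and 14184 rpm. The other 8 of the 10 miRNAs with the highest mean were miR-21-5p, let-7a-5p, miR-92a-3p, let-7f-5p, let-7i-5p, miR-100-5p, let-7b-5p and miR-221-3p. Together these 10 miRNAs took 60.6% of the miRNA reads in CC, 64.8% in Mock and 61.1% in RR. miR-205-5p gave 14.5% of the miRNA reads of RR and 6.12% of those of Mock, where miR-21-5p gave 15.9%. Members of the let-7 family differ from each other by as few as 1 base, as do miR-99a-5p and miR-100-5p, miR-103a-3p and miR-107, miR-10a-5p and miR-10b-5p, members of the miR-30 family, miR-27a-3p and miR-27b-3p, and members of the miR-320 family. How reads that match several of these were assigned is not given in the sources used here, so the level of each is uncertain.

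The title of the series ties miR-21-5p, an abundant miRNA that represses the tumour suppressor PDCD4, to radioresistance through alternative end joining, an error-prone repair of DNA breaks. miR-21-5p was close in RR and CC and far higher in the library labelled Mock. Its level was 4475 rpm in CC (95% Poisson interval 4435 to 4515), 6209 rpm in RR (6162 to 6257) and 36929 rpm in Mock (36814 to 37045). RR over CC was 1.39-fold (1.37 to 1.40), or 0.47 on the log2 scale, beside a median of 0.36 over all 208 miRNAs with a mean of 10 rpm or more. The log2 ratio was 0.10 with median-ratio scaling of the libraries, 0.15 when they were scaled without the 10 most abundant miRNAs and 0.14 as a share of the miRNA reads. Mock over CC was 8.25-fold (8.17 to 8.33), and RR was 5.95-fold lower than Mock, a ratio of 0.168 (0.167 to 0.170). miR-21-3p, cut from the other arm of the same hairpin, stood at 12.4 rpm in CC, 14.3 in Mock and 11.5 in RR. Mock over CC for miR-21-3p was 1.15-fold, with an interval of 0.905 to 1.46 that includes no change. The sequence listed for miR-21-5p, TAGCTTATCAGACTGATGTTGA, matched the MIR21 hairpin on GRCh38 chromosome 17, at 59841273 to 59841294 within a hairpin of 59841266 to 59841337. The hairpin overlaps an exon of the protein-coding gene VMP1 on the same strand. No listed miRNA lay within 2 mismatches of miR-21-5p.

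**Figure D1:**
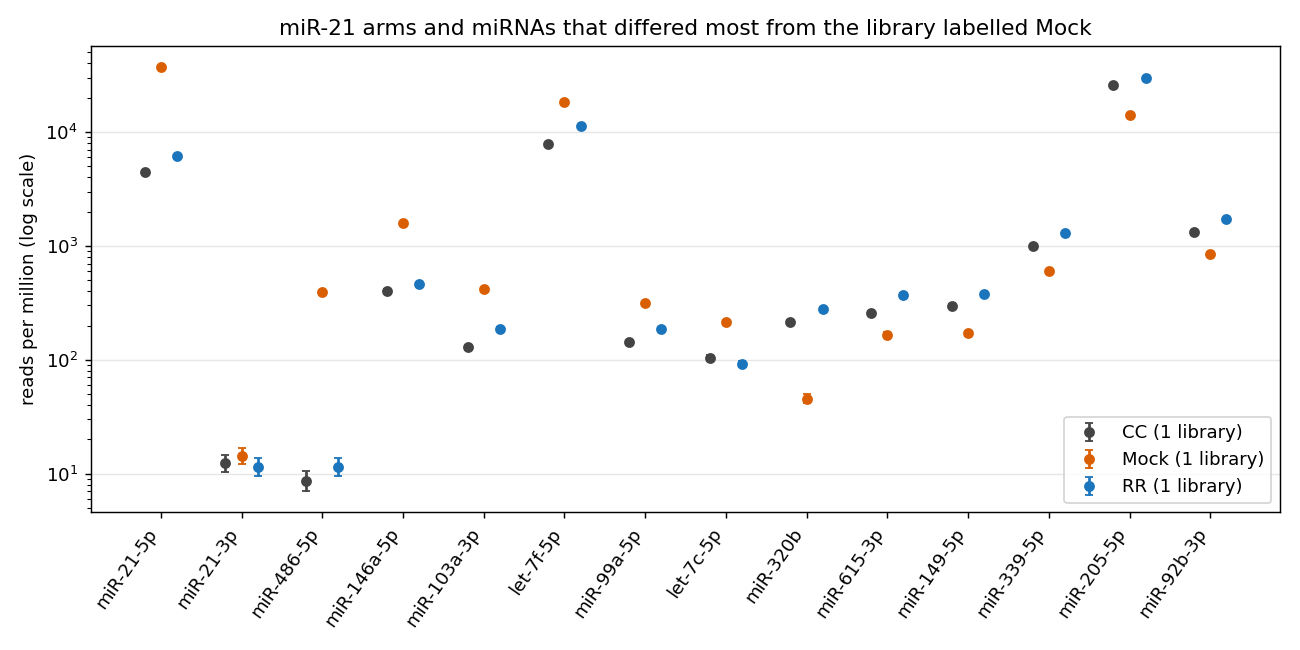
Levels of the miR-21 arms and of the miRNAs that differed most from the library labelled Mock, in rpm on a log scale, with 1 point per library and bars for the 95% Poisson interval, which is often smaller than the point. miR-21-5p and miR-486-5p lie higher in Mock (36929 and 398 rpm) than in CC and RR, while miR-21-3p lies between 11.5 and 14.3 rpm in all 3.

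RR over CC asks which miRNAs differ between radioresistant and untreated cells. The profiles of both libraries were close: of 208 miRNAs, 2 were higher in RR by 2-fold or more and 1 was lower. miR-550a-5p stood at 32.7 rpm in RR and 13.8 in CC, 2.36-fold higher (1.94 to 2.88), and miR-3182 at 30.9 and 12.8 rpm, 2.41-fold higher (1.97 to 2.97). miR-103b fell from 21.4 rpm in CC to 3.82 in RR, 5.59-fold lower (3.98 to 8.03), while miR-103a-3p, whose hairpins lie in introns of PANK2 and PANK3, was 1.46-fold higher (1.36 to 1.57). The sequence listed for miR-103b is the reverse complement of that of miR-103a-3p, which is more abundant. Whether its reads are an artefact of strand was not tested. miR-550a-5p, miR-3182 and miR-103b fell outside the rule for named miRNAs and were chosen after their values were seen. None of the 93 miRNAs with a mean of 100 rpm or more differed by 2-fold, so that the rule named none for this comparison by size. miR-27a-5p had the largest ratio among them, 1.81-fold (1.73 to 1.89), with 306 rpm in CC and 553 in RR. Across miRNAs, log2 values of RR and CC had a Pearson correlation of 0.993, where miRNAs are not independent replicates. The median ratio was 1.28-fold, and with median-ratio scaling, which took that median to -0.01, the split of 2 higher and 1 lower became 0 and 2; it was also 0 and 2 when scaled without the 10 most abundant miRNAs and as a share of the miRNA reads.

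**Figure D2:**
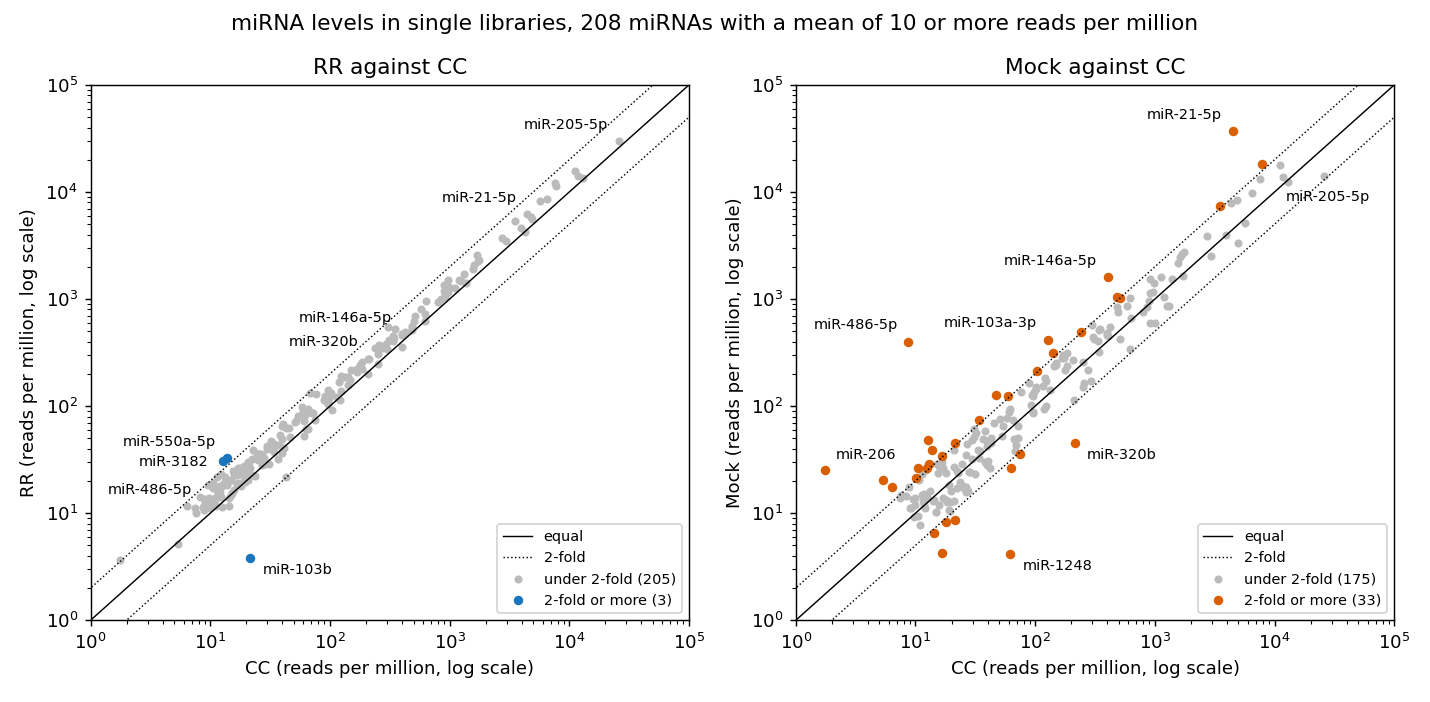
Level of each of 208 miRNAs with a mean of 10 rpm or more in RR (left) and Mock (right) against CC, in rpm on log axes, with 1 point per miRNA, a solid line for equal levels and dotted lines for 2-fold. In RR 3 miRNAs are coloured as past 2-fold, and in Mock 33; the counts use log2 values with 1 rpm added.

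Among the fixed lists with 3 or more measured members, the let-7 family and the miR-23/27/24 clusters had the highest medians in RR over CC, and no list had a member counted as past 2-fold. The let-7 family, repressors of RAS and HMGA2, had a median of 1.45-fold over its 9 members, 8 of them above 1-fold, at the 99.6th percentile of 10000 random lists of equal size and abundance. let-7i-5p was 1.61-fold higher (1.60 to 1.63), let-7e-5p 1.52-fold, let-7g-5p 1.51-fold and miR-98-5p 1.47-fold, whereas let-7c-5p had a ratio of 0.897 (0.822 to 0.979). The miR-23/27/24 clusters had a median of 1.45-fold over 7 members, at the 98.7th percentile, with miR-24-3p, which targets the histone H2AX, at 1.51-fold (1.47 to 1.54) and miR-27a-3p at 1.53-fold. On the log2 scale these medians, 0.53 and 0.54, became 0.16 and 0.19 with median-ratio scaling. Members of a family or cluster are not independent, through near-identical sequences or a shared locus, whereas the random lists draw miRNAs singly. Such a list reaches an extreme percentile more easily, here and in the other comparisons. The NF-kB and inflammation-induced miRNAs (7 measured) and the DNA repair-targeting miRNAs (13 measured) had medians of 0.40 and 0.41, at the 86.0th and 84.2nd percentiles. miR-146b-5p was 1.83-fold higher (1.35 to 2.50), at 11.7 rpm in RR.

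The oncogenic miR-17~92 cluster with its paralogues had a median log2 ratio of 0.22 over 13 members, at the 9.05th percentile. Medians were 0.20 for the cluster of miR-221 and miR-222, 0.25 for the miR-181 family, 0.30 for the miR-200 family, 0.32 for the miR-30 family, 0.36 for the squamous epithelial miRNAs, 0.38 for the cluster of miR-183, miR-96 and miR-182 and 0.40 for the miR-99/100 and miR-125 family. Median-ratio scaling moves all miRNAs alike, taking the median of all 208 from 0.36 to -0.01. The first 6 of these medians thereby turned negative, which says nothing of the lists themselves. miR-203a-3p, a miRNA of differentiating keratinocytes, was 1.72-fold higher in RR (1.46 to 2.02). miR-210-3p, induced by hypoxia through HIF-1, was 1.96-fold higher (1.79 to 2.14), at 68.1 rpm in CC and 133 in RR, and miR-210-5p was 1.13-fold (0.920 to 1.39). Of the p53-regulated miRNAs 2 of 12 were measured, miR-192-5p at 1.69-fold (1.55 to 1.85) and miR-194-5p at 1.43-fold (1.30 to 1.58), while miR-34a-5p had 1 read in CC, 7 in Mock and 6 in RR. Of the miR-29 family and the miR-15/16 family 2 members each were measured, with medians of 0.19 and 0.03.

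Mock over CC asks how cells given a single exposure differ from untreated cells. Among miRNAs with a mean of 100 rpm or more, miR-486-5p and miR-21-5p stood furthest above CC in the library labelled Mock, followed by miR-146a-5p, an NF-kB-induced brake on TRAF6 and IRAK1, and miR-103a-3p. miR-486-5p, an erythroid and muscle miRNA from an intron of ANK1, stood at 8.73 rpm in CC and 398 in Mock, 45.6-fold higher (37.1 to 56.5). miR-146a-5p was 3.95-fold higher (3.82 to 4.08), at 403 and 1591 rpm, and miR-103a-3p 3.24-fold (3.05 to 3.44). let-7f-5p was 2.32-fold and miR-99a-5p 2.23-fold higher. miR-320b was 4.68-fold lower (4.24 to 5.17), at 213 rpm in CC and 45.6 in Mock. With a mean under 100 rpm, the muscle miRNA miR-206 stood at 1.76 and 25.5 rpm, 14.4-fold higher (9.07 to 24.4), and miR-1248, whose sequence lies in a snoRNA, at 61.3 and 4.14 rpm, 14.8-fold lower (10.9 to 20.6).

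In all, 25 of 208 miRNAs were higher in Mock than in CC by 2-fold or more and 8 were lower. This split rests on the scale: it was 10 and 18 with median-ratio scaling, 10 and 19 when scaled without the 10 most abundant miRNAs, and 7 and 31 as a share of the miRNA reads. Ratios to Mock also followed the GC content of the miRNA. Across miRNAs, the Spearman correlation of GC content with the log2 ratio was -0.55 for Mock over CC and 0.05 for RR over CC. The median log2 ratio Mock over CC was 0.65 in the 80 miRNAs of lowest GC content, 0.28 in the middle 65 and -0.29 in the 63 of highest. With a linear GC trend removed, let-7f-5p fell to a log2 ratio of 0.69, under 2-fold, while miR-486-5p (5.75), miR-21-5p (2.65), miR-146a-5p (1.72), miR-103a-3p (1.63), miR-99a-5p (1.15) and miR-320b (-2.20) stayed past it. For miR-99a-5p and miR-320b this was fixed in advance, as the correction leaves miRNAs of 50% GC content unmoved. It could only raise miR-486-5p, whose GC content is 63.6%. let-7f-5p and miR-99a-5p also came under 2-fold with median-ratio scaling (0.92 and 0.85).

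**Figure D3:**
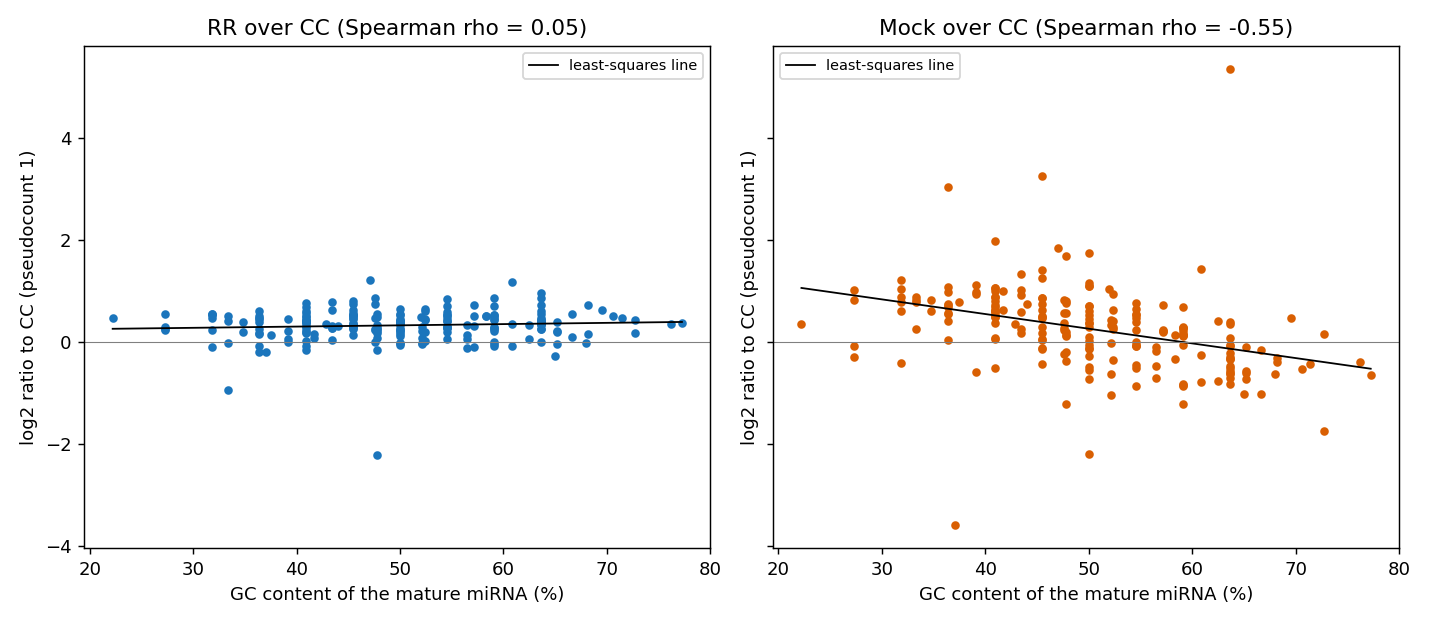
Log2 ratio of RR (left) and Mock (right) to CC, with 1 rpm added, against the GC content of the mature miRNA in percent, with 1 point for each of 208 miRNAs and a least-squares line. The Spearman correlation is 0.05 for RR and -0.55 for Mock.

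Several fixed lists stood high in Mock over CC, and all moved with the GC trend. In the let-7 family 4 of 9 members were higher by 2-fold or more (let-7c-5p, let-7f-5p, let-7g-5p and miR-98-5p), with a median log2 ratio of 0.81 at the 99.3rd percentile. Each of these 4 came under 2-fold with median-ratio scaling, at log2 ratios of 0.75, 0.92, 0.78 and 0.74. The NF-kB and inflammation-induced miRNAs had 3 of 7 members higher, namely miR-21-5p, miR-146a-5p and miR-146b-5p, with a median of 0.83 at the 97.9th percentile. The log2 ratio of miR-146b-5p, 1.33, came under 2-fold as a share of the miRNA reads (0.87) and with a pseudocount of 10 (0.75). Among the DNA repair-targeting miRNAs 2 of 13 were higher, miR-103a-3p and miR-99a-5p, and 1 was lower, miR-193b-3p (2.39-fold, 2.07 to 2.75; -0.96 on the log2 scale without the GC trend), with a median of 0.77 at the 99.2nd percentile. The cluster of miR-221 and miR-222 had a median of 0.94 at the 95.8th percentile and no member past 2-fold. Without the GC trend the 4 medians were 0.52, 0.43, 0.43 and 0.74, beside 0.32 for all miRNAs. They kept their sign under every scaling tried. As scaling moves all miRNAs alike, this says only that they lay well above the deposited median of all miRNAs, 0.28. The median of the miR-17~92 cluster and its paralogues was 0.35 but -0.13 as a share of the miRNA reads, where that of all miRNAs went from 0.28 to -0.22. Medians of the miR-30 family (0.23) and the squamous epithelial miRNAs (0.27) turned to -0.07 and -0.03 with median-ratio scaling, and that of all miRNAs to -0.01. For the remaining lists with 3 or more measured members, medians were 0.49 in the miR-200 family, 0.52 in the miR-23/27/24 clusters, 0.59 in the miR-99/100 and miR-125 family, 0.68 in the cluster of miR-183, miR-96 and miR-182 and 0.70 in the miR-181 family, and as a share of the miRNA reads they fell to 0.00, 0.01, 0.10, 0.17 and 0.21. miR-16-5p, of the miR-15/16 family, was 2.71-fold higher in Mock (2.44 to 3.00), miR-29b-1-5p 2.11-fold higher (1.67 to 2.68) and miR-210-5p 3.93-fold lower (2.82 to 5.57), and on the log2 scale miR-29b-1-5p came under 2-fold with median-ratio scaling (0.73), miR-16-5p as a share of the miRNA reads (0.91) and miR-210-5p with a pseudocount of 10 (-0.90).

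RR over Mock sets repeated against single exposure. Among miRNAs with a mean of 100 rpm or more, miR-486-5p was 34.7-fold lower in RR (ratio 0.0288, 0.0238 to 0.0345), miR-21-5p 5.95-fold lower, miR-146a-5p 3.44-fold lower (3.33 to 3.55), let-7c-5p 2.32-fold lower and miR-103a-3p 2.22-fold lower. miR-320b was 6.10-fold higher in RR (5.54 to 6.73), miR-615-3p, from the HOXC locus, 2.24-fold (2.12 to 2.38), miR-149-5p, from an intron of GPC1, 2.22-fold, miR-339-5p 2.18-fold, miR-205-5p 2.09-fold (2.08 to 2.10) and miR-92b-3p 2.00-fold. With a mean under 100 rpm, miR-206 was 7.02-fold lower in RR (4.99 to 10.1), miR-320c 3.94-fold lower (2.91 to 5.41) and miR-1248 12.8-fold higher (9.43 to 17.9). Both arms of miR-210 were higher, miR-210-3p 3.53-fold (3.16 to 3.96) and miR-210-5p 4.44-fold (3.20 to 6.29). Counts were 17 higher and 10 lower of 208, and 25 and 8 as a share of the miRNA reads. The Spearman correlation of the log2 ratio with GC content was 0.60, and without the GC trend 7 were higher and 7 lower. Of the miRNAs named here, miR-615-3p (0.74), miR-149-5p (0.80), miR-339-5p (0.65), miR-205-5p (0.92), miR-92b-3p (0.58) and let-7c-5p (-0.92) then came under 2-fold on the log2 scale. With median-ratio scaling miR-205-5p (0.99) and miR-92b-3p (0.93) did so, and as a share of the miRNA reads miR-103a-3p (-0.97).

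Lists low in RR over Mock were the cluster of miR-221 and miR-222, with a median log2 ratio of -0.75 at the 1.92nd percentile, the NF-kB and inflammation-induced miRNAs (-0.55, 3.11th percentile) and the DNA repair-targeting miRNAs (-0.27, 5.95th percentile). Without the GC trend they stood at -0.47, -0.26 and -0.20. The let-7 family had a median of -0.18 and of 0.16 without that trend. Medians of the remaining lists with 3 or more measured members ran from -0.49 in the cluster of miR-183, miR-96 and miR-182 to 0.09 in the miR-30 family.

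A miRNA specific to the radioresistant library would differ from both others. Only miR-103b did so by 2-fold or more, at 3.82 rpm in RR, 8.65 in Mock and 21.4 in CC, and it did not once the GC trend was removed, when the count was 0. By the same measure CC stood apart for 3 miRNAs and Mock for 14, of which 8 were higher and 6 lower. These counts depended on the scale: Mock stood apart for 24 as a share of the miRNA reads and 8 with a pseudocount of 10, CC for 1 and 0, and RR for 2 with median-ratio scaling. The 14 were miR-486-5p, miR-206, miR-21-5p, miR-146a-5p, miR-320c, miR-103a-3p, miR-16-5p and let-7c-5p, all higher, and miR-1248, miR-320b, miR-210-5p, miR-193b-3p, miR-296-5p and miR-139-5p, all lower. Without the GC trend Mock stood apart for 10, and let-7c-5p, miR-193b-3p, miR-296-5p and miR-139-5p were no longer among them. Pearson correlations of log2 values across miRNAs were 0.956 for CC with Mock and 0.960 for RR with Mock. Libraries simulated as unchanged gave 0 in each of these counts, which shows what counting error alone yields and nothing of differences between cultures.

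Markers of other cell types differed in level. Those of fibroblasts and mesenchyme, such as miR-143-3p, summed to 6.96 rpm in CC, 6.87 in Mock and 6.97 in RR. Most of this was miR-143-3p, while miR-199a-5p of the same list had 2, 12 and 0 reads (Mock over CC 6.08-fold, 1.35 to 55.9). The hepatocyte miRNA miR-122-5p stood at 4.46, 5.45 and 2.96 rpm. Blood cell miRNAs summed to 9.56, 410 and 12.3 rpm, nearly all of it miR-486-5p. The endothelial miRNA miR-126-3p stood at 53.9, 65.8 and 80.5 rpm, and the neuronal list, which carcinoma lines also express in part, had a median log2 ratio of 0.25 for RR over CC and 0.83 for Mock over CC, with miR-9-5p at 170 rpm in CC, 303 in Mock and 224 in RR. The RR over CC median of that list was -0.11 with median-ratio scaling, against -0.01 for all miRNAs, and its Mock over CC median fell to 0.36 without the GC trend and to 0.32 as a share of the miRNA reads. Of the muscle miRNAs, miR-1-3p was at 338, 319 and 404 rpm. The imprinted 14q32 cluster was nearly silent: 25 of its 59 listed members were in the table and they summed to 4.27 rpm in CC, 6.49 in Mock and 2.58 in RR. The placental 19q13 cluster had 1 of 37 members in the table, with a single read in RR. The list of the miR-371-373 cluster, which also holds miR-302 members and miR-367-3p, had 0 of 10. Of the miRNA names that overlap snoRNAs or other structural RNAs 2 of 18 were measured, miR-1248 and miR-664a-3p, the latter at 19.5 rpm in CC, 12.6 in Mock and 19.5 in RR.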

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

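Values as a share of the miRNA reads, without the GC trend, with the mean of CC and RR alone, and those for Mock or CC apart were computed only after the results had been seen. All 33 ratios of 2-fold or more among the named miRNAs kept their direction under the 6 other log scales. This was close to fixed in advance, as the ratios were picked at 2-fold or more and the rescalings moved the median of all miRNAs by less. Past 2-fold, 33 stayed with a pseudocount of 0.1, 27 with 10, 24 with median-ratio scaling, 26 when scaled without the 10 most abundant miRNAs, 23 as a share of the miRNA reads and 21 without the GC trend. Counts of higher and lower miRNAs follow in the order RR over CC (2 and 1 as reported), RR over Mock (17 and 10) and Mock over CC (25 and 8), then miRNAs with RR (1), Mock (14) and CC (3) apart. With a pseudocount of 10 they were 0 and 1, 8 and 8, 13 and 3, then 0, 8 and 0. Median-ratio scaling gave 0 and 2, 12 and 10, 10 and 18, then 2, 16 and 1. Scaling without the 10 most abundant gave 0 and 2, 17 and 9, 10 and 19, then 1, 19 and 1. As a share of the miRNA reads they were 0 and 2, 25 and 8, 7 and 31, then 1, 24 and 1. Without the GC trend they were 2 and 1, 7 and 7, 17 and 4, then 0, 10 and 3. With more or fewer miRNAs tested, as the filter sets, a mean of 1 or more (390 miRNAs) gave 5 and 2, 31 and 19, 44 and 13, then 2, 24 and 4; no filter (1149) gave 6 and 2, 33 and 24, 46 and 14, then 2, 26 and 4; and a mean of 100 or more (93) gave 0 and 0, 6 and 5, 11 and 1, then 0, 6 and 0. By construction, a 1.5-fold threshold raised them to 28 and 2, 46 and 30, 70 and 26, then 8, 51 and 15, and a 4-fold threshold left 0 and 1, 2 and 3, 3 and 2, then 0, 5 and 0. With the mean of CC and RR alone, RR over CC gave 2 and 2. A pseudocount of 0.1 and the request that the counting interval exclude 1 moved no count by over 1.5 times. The log2 ratio of miR-21-5p, RR over CC, reported as 0.47, was 0.10 with median-ratio scaling, 0.15 when scaled without the 10 most abundant miRNAs, 0.14 as a share of the miRNA reads and 0.51 without the GC trend. The first 3 of these take out the shift of all miRNAs, whose median of 0.36 became -0.01, 0.04 and 0.03; beyond this and the filters and thresholds, the cause was not tested. Of the alternative values, 672 for named miRNAs and 133 for lists stayed within the counting interval or the standard error of the list, and 588 and 101 did not. That 0 changed sign from 2-fold or more was likewise close to fixed in advance. All names in the table were of human mature miRNAs, each listed once, so that leaving out predicted miRNAs and summing repeated entries had nothing to act on. Depth limits ratios mainly for miRNAs with a few reads, such as miR-34a-5p.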

Other observations

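All tests of explanations given in this part were chosen only after the results had been seen, as were the minimum of 10 reads for a marker and the bounds of 1 and 50 percent used in them. miR-1-3p and miR-133a-3p, which are made from shared transcripts in muscle, were far apart in these cells: miR-1-3p had 3643 reads in CC and 3388 in Mock, and miR-133a-3p 11 and 7. Arms of a hairpin also moved apart. Of 38 hairpins with both arms measured, miR-21 had the widest gap between arms for Mock over CC, 2.86 on the log2 scale against a median of 0.40, followed by miR-185 at 1.41, where miR-185-5p was 1.63-fold higher (1.53 to 1.74) and miR-185-3p had a ratio of 0.598 (0.491 to 0.726). For RR over CC the widest gap, 0.79, was that of miR-210. miR-320b differs from miR-320a-3p by G21A, counted from the 5' end with the base of miR-320a-3p first. It stood at 12.4% of miR-320a-3p in CC, 2.80% in Mock and 12.2% in RR, while miR-320c, of the same family, was 3.77-fold higher in Mock than in CC (2.81 to 5.13).

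The library labelled Mock stood apart from both others for 14 miRNAs, against 1 for RR, although radioresistance is what the design sets out to study. A difference in total depth is argued against, since its 10632785 reads lay between those of RR and CC. Its 2462835 miRNA reads were the most. Taking the share of the miRNA reads, where 24 miRNAs stood apart, only rescales the values and cannot test this. All 14 had counting intervals that excluded 1, which take the reads of each library into account. With 2-fold differences at a mean of 10 rpm or more this was close to fixed in advance and adds no support. A linear GC trend of the library as the whole cause is argued against as well, as 10 of the 14 stayed apart without it. Of these, miR-320b and miR-320c, of 50% GC content, could not move, and miR-486-5p and miR-1248 could only move further apart. The argument rests on miR-21-5p, miR-146a-5p, miR-103a-3p, miR-16-5p, miR-206 and miR-210-5p, which moved nearer to the other libraries and stayed past 2-fold. A bias of another form may add to them. It stays open whether the labels of Mock and RR were exchanged: log2 values of CC correlated at 0.993 with RR and 0.956 with Mock, which a large effect of the exposure in the library as labelled would give as well, so these cannot be told apart. A response to irradiation, differences between single-cell clones and handling of the single library also remain open and were not tested.

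miR-21-5p was 8.25-fold higher in Mock than in CC. GC bias as its cause is argued against by a log2 ratio of 2.65 that remained without the GC trend. More of the whole hairpin is argued against by miR-21-3p, whose fold had an upper bound of 1.46, under the lower bound of 8.17 for miR-21-5p; this leaves a change in the stability of one arm, or in how it was captured, open and untested. RNA of fibroblasts or white blood cells, which hold much miR-21-5p, is argued against because their abundant miR-143-3p, miR-199a-5p, miR-142-3p and miR-142-5p together came to 0.0209% of the additional 32454 rpm. An effect of the exposure may be named as a hypothesis only, given that the exchange of labels is open.

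Blood miRNAs were higher in Mock: besides miR-486-5p, miR-451a had 8 reads in CC and 82 in Mock (10.4-fold, 5.03 to 24.9), and miR-144-3p had 0 and 26 reads, with a counting interval of its fold from 6.64 upward. Of white blood cells, miR-142-3p had 1 read in CC and 8 in Mock and miR-142-5p 0 and 5. miR-150-5p of the same list had 0 and 8. The minimum of 10 reads left these out of the marker count below. For miR-486-5p, of 63.6% GC content, removing the GC trend could only raise the log2 ratio, to 5.75, which is no test of GC bias. As deposited it ran against that trend, under which miRNAs of high GC content were lower in Mock. RNA of adult muscle is argued against by miR-133a-3p, whose upper bound was 5.72% of the additional miR-206. That presumes that miR-133a-3p is captured as well as miR-206, which was not tested. miR-133b, of the same muscle list, had 0 reads in CC and 5 in Mock. RNA of red blood cells or serum may be a source. Routes such as the culture medium or carry-over from another library were not told apart. All 3 blood markers with 10 or more reads had an interval above 1, while 14 markers of other cells had a median of 1.22-fold. This is no independent support, since miR-451a and miR-144-3p reached 10 reads only through Mock, so their intervals could hardly include 1. Some markers of other cells also had intervals above 1, among them miR-9-5p (lower bound 1.68) and miR-126-3p (1.09). Against RNA of red blood cells as the whole account, miR-206 is no blood cell miRNA and was 14.4-fold higher. It does not speak against serum, as no serum profile was used here. miR-486-5p exceeded miR-451a by 51.6-fold, which argues neither way, as no blood profile was used here. Whether the exposure raised these miRNAs in the cells was not tested.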
